A study of Mus musculus with 8 samples.

How the data were processed

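RNA of brain cortex from mouse embryos at embryonic day 16 was extracted with a Qiagen RNeasy kit, per the labels' protocols. From 120 ng of total RNA, cDNA was made with the Ambion WT Expression kit and fragmented and biotinylated with the GeneChip WT terminal labelling kit, per the labels' protocols. The labels describe a mixed strain background. The submitters' processing notes name Affymetrix Expression Console and the mouse genome build mm8, and the series text names a plain unpaired t-test run in GeneSpring. The steps of background correction and summarisation are not given in the sources used here.

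The values used are those of the deposited series table, 28853 probe sets on 8 arrays with 0 missing values. The authors deposited log2 values as far as the range shows, since no source states the base of the logarithm. Each probe set had a median over the 8 arrays within 5e-07 of 0, so the deposited values are centred per probe set. Another base would rescale every difference by the same factor and leave the tests as they are. Centred values keep no brightness, so no filter on dim probe sets could be made, and signal over background is unknown. No pair of arrays held identical values, and array medians are given with the results.

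Probe sets were named through the platform annotation. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 5443 were unnamed here. Symbols were updated through Entrez identifiers to the RefSeq gene table of GRCm38.p6, which held 21698 of the 21789. That assembly differs from the build in the processing notes, so no coordinates are given. Probe sets with several genes were left out, and the probe sets of a gene were averaged, which concerned 999 of the 19938 genes tested. The mean was the rule fixed beforehand for centred values.

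Groups and replicate numbers came from the sample labels, 4 control arrays and 4 arrays of bitransgenic embryos. The main test was limma's linear model with empirical Bayes moderation, without trend or robust fitting and without covariates, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are VEGF minus control. An SE of a single gene is that of the moderated fit, and an SE of a mean over several genes is that of an ordinary linear model. The prior had 3.12 degrees of freedom beside 6 residual ones, and the median residual SD was 0.0752. Vegfa was also compared with an exact two-sided permutation test. Gene lists were tested with limma's camera, two-sided, at a preset inter-gene correlation of 0.01 and adjusted over 30 lists. The lists held 13 sets of cell type or tissue markers and 17 other sets, mostly pathways, Vegfa was in none, and they may share members. Members were also tested with adjustment over the list alone. Camera compares a list with the other genes, while fry tests whether the genes of a list move one way on balance. In its mixed form, fry tests whether they change in either direction. Relations between list means were tested with exact permutation for Pearson's r and Spearman's rho, and 3 relations were computed. The 3 pairs were not among the tests fixed beforehand. Their adjustment covers these 3 alone, not all pairs of the 30 lists, and the permutation ignored the groups. Sex patterns were read from Xist and the measured Y-linked genes.

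Named genes followed a rule fixed before the data were examined. Vegfa came first. As no gene passed the threshold, the 5 genes with the smallest p in each direction were named, leaving out predicted genes and genes named by clone. Each list contributed its members of smallest p, up to 4 in lists that passed and 2 in the others. A set of genes was named whatever its values (Kdr, Flt1, Cdh5, Pecam1, Pdgfrb, Gfap, Ctsb, Mmp9 and Hbb-y).

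The fit was tested on simulated data with the spread of these arrays, 19938 genes of which 200 were changed. Of 67 genes changed by 0.2 on the log2 scale 32.8% were recovered, of 67 changed by 0.5 86.6%, and of 66 changed by 1 100%. The changed genes were drawn at random, so these shares do not hold for genes of wide spread. In these data 8 genes differed by more than 1 and 0 genes passed, and Lhx6 at -1.23 had an adjusted p of 0.243 in limma. The shares therefore do not show that changes of 0.5 or 1 are absent. Of 155 calls 9 were wrong. With no gene changed there were 0 calls, and with 1 list lowered camera called that list alone. The simulated genes varied independently, while in these data the median estimated correlation within lists was 0.282. The simulation therefore cannot show how camera at its preset correlation behaves on these lists.

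Alternatives fixed before the data were examined were the replicate number as a block, arrays centred on their medians, quantile normalization, a trended and robust prior, array weights, a sex index and the erythroid list mean as covariates, the methods' t-test, all probe sets tested alone, camera with an estimated correlation, fry, and leaving out each array in turn. Added after seeing the data were the first probe set of each gene, the thalamus and hippocampus list mean as a covariate, leaving out the 3 arrays with high thalamic markers, leaving out the 3 arrays with a female pattern, and exact permutation of list means. Computations used R 4.3.3 with limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9.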

Results

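Whole-transcript expression was measured on 8 Affymetrix arrays from the brain cortex of mouse embryos at embryonic day 16. The labels put 4 arrays in a wild-type control group and 4 in a group of bitransgenic embryos, in which a tetracycline-controlled transactivator under the Gfap promoter drives a TetO-linked VEGF-A transgene. VEGF-A is the main growth factor for blood vessels, and the comparison asks which genes of the embryonic cortex differ when it is overexpressed. With wild-type controls on a mixed strain background, VEGF-A cannot be told apart from the transactivator, the transgene insertions or other differences in genotype. The deposited table holds 28853 probe sets on a log scale, read here as log2, each centred on its own median over the 8 arrays. Values are therefore relative to that median, no absolute level is kept, and a fold holds only if the base is 2. Array medians lay between -0.0091 in VEGF 2 and 0.0154 in control 2, and the interquartile range of an array's values lay between 0.061 in control 4 and 0.142 in VEGF 2. Arrays are named by group and replicate number. Xist and the Y-linked genes gave a female pattern in 1 of 4 control arrays and in 2 of 4 arrays of the VEGF group. The number of arrays limits the precision, and nothing in the labels says that the 4 arrays of a group come from separate litters or from pooled or single embryos. The p-values measure the spread between these arrays. Xist was at 5.27 in control 3 and between -0.19 and 0.14 in the other control arrays. It was at 5.42 and 5.11 in VEGF 2 and VEGF 3, against -0.16 and -0.19 in VEGF 1 and VEGF 4. These values argue against a purely technical spread within a group, though arrays of the same sex pattern may still share a source.

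Vegfa itself, the gene of the transgene, did not separate the groups. Its mean was -0.04 ± 0.08 in control (SD, n = 4) and 0.01 ± 0.06 in the VEGF group (SD, n = 4), a difference of 0.05 on the log2 scale with an SE of 0.051. Across the 8 arrays the values spanned 0.195, and no array stood apart. The exact two-sided permutation test gave p = 0.343, and limma gave an adjusted p of 0.748. Vegfa was read by 1 probe set, and whether its probes lie in the part carried by the transgene is not given in the sources used here. Vegfa thus does not check the labels, and the arrays are called VEGF-labelled from here on. Every direction below is that of the VEGF-labelled arrays relative to the control arrays.

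Among single genes, Hmox1, the heme-degrading enzyme heme oxygenase 1, stood farthest above control relative to its spread. Its mean was -0.31 ± 0.12 in control and 0.37 ± 0.15 in the VEGF-labelled arrays (SD, n = 4 each), a difference of 0.68 with an SE of 0.084, or 1.61-fold. The next genes on the higher side were Lyz2, a lysozyme of macrophages and other myeloid cells, with 0.44, Polk, a translesion DNA polymerase, with 0.26, the G1 cyclin Ccnd1 with 0.27 and the fucosyltransferase Fut9 with 0.32. On the lower side they were the potassium channel subunit Kcnab3 with -0.27, Zswim4 with -0.28, the RNA methyltransferase Nsun3 with -0.25, the netrin receptor Unc5d with -0.53 and the lysosomal membrane protein Mfsd8 with -0.26. In each of these 10 genes the 4 VEGF-labelled arrays lay entirely outside the range of the 4 control arrays.

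None of these differences passed the test over all genes. Of 19938 genes tested with limma, 0 passed an adjusted p of 0.05, and the lowest adjusted p was 0.219. At an unadjusted p under 0.05 there were 2484 genes, 921 higher and 1563 lower, where chance alone would give 996.9. The methods' t-test gave 2114 genes at its unadjusted threshold and 0 after Benjamini-Hochberg adjustment. The 2 groups did not overlap in 1364 genes, 425 higher and 939 lower, which is 6.84% of the genes against 2.86% by chance. Both chance figures are averages, and counts of genes that vary together can lie far from them. In each count 3 of the 35 splits of the 8 arrays, the real one included, gave as many genes. Neither count therefore shows an excess over chance. Differences were small throughout, with 71 genes beyond 0.5 on the log2 scale in either direction, 24 of them higher and 47 lower, and 8 beyond 1. The result depended on VEGF 4. Without that array 10 genes passed, with Hmox1 at 0.74 (adjusted p = 0.035) and the lymphangiogenic ligand Vegfc at 0.40 (adjusted p = 0.035) higher, and Unc5d at -0.61 (adjusted p = 0.029) and the hypoxia-responsive gene Ndrg1 at -0.78 (adjusted p = 0.029) lower among them. Over all alternatives the adjusted p ranged from 0.035 to 0.616 for Hmox1 and Vegfc, from 0.029 to 0.616 for Unc5d and from 0.029 to 0.687 for Ndrg1. The count at an unadjusted p was 1526 without control 1 and 1627 without control 4.

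Gene lists fixed beforehand were tested as groups. With limma's camera test at its preset correlation, 9 of 30 lists shifted at an adjusted p under 0.05, 6 upwards and 3 downwards. With a correlation estimated from the data no list passed, with adjusted p = 0.522 for 8 of these lists and adjusted p = 0.582 for synapse and neuronal maturation. The directional fry test and the exact permutation test of list means also called 0 lists. The mixed fry test, which gives no direction, passed for interneurons (adjusted p = 0.037) and projection neurons (adjusted p = 0.049), but not for the other lists that camera called. It also passed for the iron and heme (adjusted p = 0.0022), astrocyte (0.011), cathepsin (0.011), microglia (0.014) and protease (0.021) lists, which camera did not call. Exact tests of 4 against 4 arrays have 70 arrangements and a smallest p of 0.0286, which no longer passes after adjustment over the 30 lists.

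The interneuron and ventral forebrain list had the largest downward shift. All 19 measured members, of 21, were lower, with a median difference of -0.35 (camera, adjusted p = 9.9e-12, and adjusted p = 0.522 with an estimated correlation). The mean of the list was 0.19 ± 0.11 in control and -0.26 ± 0.24 in the VEGF-labelled arrays (SD, n = 4 each), and the 2 groups did not overlap (exact permutation p = 0.0286, adjusted p = 0.381). Lhx6, the transcription factor that specifies interneurons of the medial ganglionic eminence, differed by -1.23 with an SE of 0.206, or 0.426-fold. Dlx2 and Dlx5, homeobox genes of ventral progenitors and interneurons, differed by -0.62 and -0.50, and Slc32a1, the vesicular GABA transporter, by -0.34. Adjusted over the list alone, 11 of the 19 members were lower and 8 did not pass, against 0 over all genes. The spread within the VEGF-labelled group came largely from VEGF 3, whose list mean was -0.62.

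Projection neuron genes also fell as a list. Of 18 measured members, of 20, 15 were lower and the median difference was -0.18 (camera, adjusted p = 9.4e-06, and adjusted p = 0.522 with an estimated correlation). Adjusted over the list alone, 5 members were lower and 13 did not pass, against 0 over all genes. They included Unc5d, marking upper-layer and multipolar migrating neurons, and Bcl11b, Sox5 and Mef2c, transcription factors of cortical neuron differentiation, which differed by -0.48, -0.50 and -0.51. VEGF 4 lay at or close to the control values in all of the last 3 genes. The list of synaptic and neuronal maturation genes had a median of -0.16, with 11 of 13 measured members lower (camera, adjusted p = 0.0072, and adjusted p = 0.582 with an estimated correlation). No member of it passed over all genes or adjusted over the list alone. Camk2a, a kinase of excitatory synapses, differed by -0.35, the vesicle release protein Snap25 by -0.19, the vesicle protein Syp by -0.16 and the calmodulin-binding Nrgn by -0.21. This list did not pass without VEGF 3, where its median was -0.087 (camera, adjusted p = 0.064).

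The thalamus and hippocampus list, which marks neighbouring forebrain tissue, rose, with 7 of 8 members higher and a median of 0.40 (camera, adjusted p = 0.0036, and adjusted p = 0.522 with an estimated correlation), though no member passed over all genes or adjusted over the list alone. The thalamic transcription factor Lhx9 differed by 0.52, Lef1 by 0.36 and the calcium-binding Calb2 by 0.36, while Zbtb20, a transcription factor of the hippocampus, differed by -0.24. The list mean was 0.69 in VEGF 1, 0.59 in VEGF 2 and 0.10 in VEGF 3 but -0.22 in VEGF 4, and it was 0.27 in control 2 against -0.31, -0.17 and -0.29 in the other control arrays. Across the 8 arrays it went against the projection neuron list mean, with Pearson's r = -0.890 (exact permutation p = 0.0050, adjusted p = 0.0075 over 3 relations) and Spearman's rho = -0.929 (exact permutation p = 0.0022, adjusted p = 0.0067). Without VEGF 1 and VEGF 2, the 2 arrays farthest from the median, r was -0.726. Against the interneuron list r was -0.370 (exact permutation p = 0.376, adjusted p = 0.376) and rho was -0.619 (exact permutation p = 0.115, adjusted p = 0.115), and r was -0.481 without VEGF 3 and control 1. With 4 arrays, each group is too small for a correlation of its own, and no correlation with the group means removed was run. These relations were not fixed beforehand, and a shift of both lists between the groups is part of them. With the thalamus and hippocampus list mean as a covariate, the median of the projection neuron list was -0.080 (camera, adjusted p = 0.017) and that of the interneuron list -0.43 (adjusted p = 1.6e-09). Without control 2, VEGF 1 and VEGF 2, the 3 arrays with the highest thalamic values, 1 gene passed over all genes, AA388235 at -2.35 (adjusted p = 0.00033). That gene was named after its value was seen. It was low only in VEGF 3 and VEGF 4, at -2.16 and -2.27, while VEGF 1 and VEGF 2, at -0.013 and -0.024, lay close to control. Its pass thus follows from which arrays were left out, and over all 8 arrays its unadjusted limma p was 0.042. Without the same 3 arrays the medians of the interneuron, thalamus and unfolded protein response lists were -0.54, 0.23 and 0.11.

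**Figure D1:**
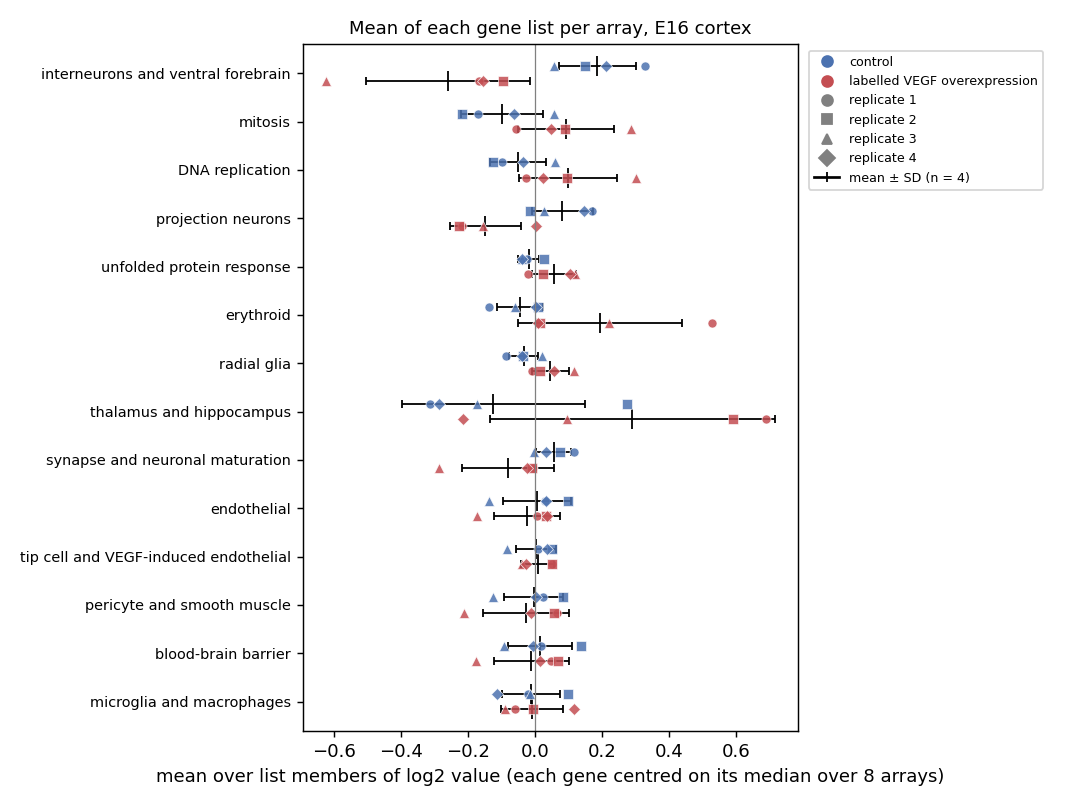
Mean of each gene list per array, on the log2 scale relative to the median over the 8 arrays, for the 9 lists that passed the camera test at its preset correlation and for 5 vascular, barrier and microglial lists that did not. Points are arrays, horizontal marks are group means and bars are SD (n = 4 per group). The interneuron list lies below control in all 4 VEGF-labelled arrays, from -0.10 to -0.62, while the thalamus and hippocampus list spans -0.22 to 0.69 in them.

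Cell-cycle genes rose as lists. All 19 measured members of the mitosis list were higher, with a median of 0.21 (camera, adjusted p = 1.6e-10, and adjusted p = 0.522 with an estimated correlation). Ccnb2 and Cdk1, a mitotic cyclin and the kinase such cyclins activate, differed by 0.21 each, the chromosomal passenger kinase Aurkb by 0.15 and its partner Birc5 by 0.25. All 14 members of the DNA replication list were higher as well, with a median of 0.14 (camera, adjusted p = 2.6e-06, and adjusted p = 0.522 with an estimated correlation). Mcm3 and Mcm4, subunits of the replicative helicase, differed by 0.26 and 0.19, thymidylate synthase Tyms by 0.20 and the origin-licensing factor Cdc6 by 0.14. In both lists no member passed over all genes or adjusted over the list alone. VEGF 3 had the highest mean in both lists, 0.29 for mitosis and 0.30 for DNA replication, and without that array the medians were 0.11 and 0.071. In DNA replication the 3 arrays with a female pattern, control 3, VEGF 2 and VEGF 3, had the 3 highest means, as they had in mitosis, and without them the medians were 0.16 for mitosis (camera, adjusted p = 3.5e-10) and 0.084 for DNA replication (adjusted p = 0.00014). Across the 8 arrays the mitosis list mean went against that of the synapse list, with Pearson's r = -0.908 (exact permutation p = 0.0014, adjusted p = 0.0042 over the same 3 relations) and Spearman's rho = -0.857 (exact permutation p = 0.011, adjusted p = 0.016), and r was -0.869 without VEGF 3 and control 2. This pair was not fixed beforehand either, and both lists differed between the groups, so that difference is part of r.

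Radial glia, the neural stem cells of the embryonic cortex, had 13 of 18 marker genes higher and a median of 0.057 (camera, adjusted p = 0.0030, and adjusted p = 0.522 with an estimated correlation). Adjusted over the list alone, 2 members were higher, 1 was lower and 15 did not pass, and none passed over all genes. Hopx, a marker of outer and dorsomedial radial glia, differed by 0.68 with an SE of 0.127, and Pax6 and Lhx2, transcription factors of cortical progenitors, by 0.23 and 0.18. The secreted protein Mfge8 differed by -0.37. The mean of the radial glia list was 0.12 in VEGF 3 and 0.056 in VEGF 4, but -0.0082 in VEGF 1 and 0.014 in VEGF 2, against -0.086 to 0.021 in control. The median of the list was 0.035 without control 1 (camera, adjusted p = 0.020), 0.13 without the 3 arrays with high thalamic values (adjusted p = 0.00069) and 0.097 with the thalamus list mean as a covariate (adjusted p = 6.1e-05). Intermediate progenitor genes did not pass (11 measured, median -0.024, camera, adjusted p = 0.73), and of these the Notch ligand Dll3 was lower by the test adjusted over the list alone, at -0.23, while Rhbdl3 differed by -0.19. Their median was -0.083 without VEGF 3 and -0.078 without VEGF 4, but 0.023 without VEGF 1 and 0.088 without the 3 arrays with high thalamic values.

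Endoplasmic reticulum chaperone genes and red cell genes also rose as lists. The unfolded protein response list had 11 of 15 members higher and a median of 0.072 (camera, adjusted p = 0.00066, and adjusted p = 0.522 with an estimated correlation). Hspa5, the chaperone BiP, differed by 0.22 and was higher adjusted over the list alone, the other 14 members did not pass, and none passed over all genes. Creld2 differed by 0.19, the chaperone Hsp90b1 by 0.17 and asparagine synthetase Asns by 0.085. The mean of this list was 0.12 in VEGF 3 and 0.10 in VEGF 4, but -0.020 in VEGF 1 and 0.025 in VEGF 2, against -0.039 to 0.026 in control. The erythroid list, of which 13 of 21 members were measured, had 11 higher and a median of 0.14 (camera, adjusted p = 0.00066, and adjusted p = 0.522 with an estimated correlation), with no member past the test over all genes or adjusted over the list alone. Alas2, the first enzyme of heme synthesis in red cells, differed by 0.83 with an SE of 0.276, the embryonic globin Hbb-y by 0.44, and the blood group membrane proteins Rhd and Rhag by 0.22 and 0.14. The erythroid list mean was 0.53 in VEGF 1 and 0.22 in VEGF 3 but 0.016 in VEGF 2 and 0.0088 in VEGF 4. The median was 0.083 without VEGF 1 (camera, adjusted p = 0.011), 0.080 with the thalamus list mean as a covariate (adjusted p = 0.018) and 0.24 without the 3 arrays with a female pattern (adjusted p = 8.3e-05). With the erythroid list mean as a covariate the synapse list, with a median of -0.16, and the thalamus list, with 0.20, did not pass (camera, adjusted p = 0.14 and 0.18). The iron, heme and oxidative response list, to which Hmox1 belongs, did not pass (17 measured, median 0.013, camera, adjusted p = 0.11), though it did with array weights (median 0.035, adjusted p = 0.037). Adjusted over the list alone, Hmox1 and the glutathione synthesis subunit Gclm, at 0.18, were higher and 15 members did not pass.

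**Figure D2:**
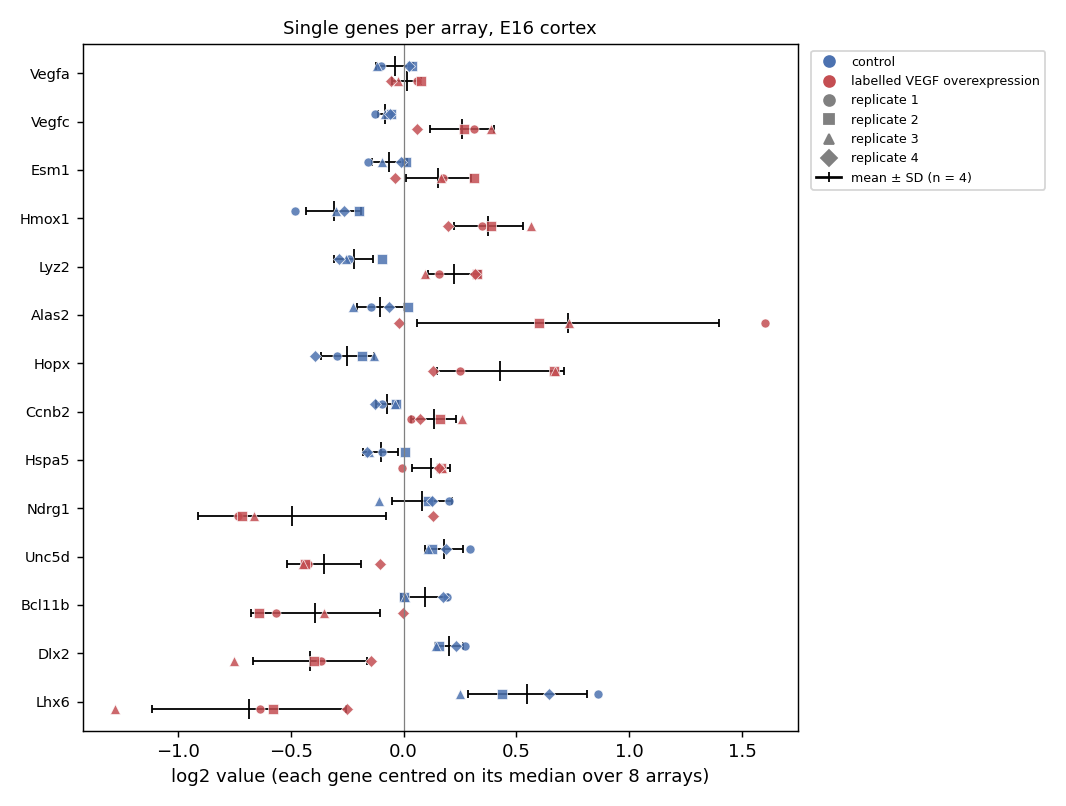
Log2 value per array, relative to the gene's median over the 8 arrays, of 14 genes named in the text. Points are arrays, horizontal marks are group means and bars are SD (n = 4 per group). The 4 VEGF-labelled values lie above all control values in Hmox1 and below them in Lhx6 and Dlx2, and the groups overlap in Vegfa.

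No vascular list passed the test on the 8 arrays. The endothelial list, with all 34 members measured, had a median of -0.016 (camera, adjusted p = 0.84), and no member passed over all genes or adjusted over the list alone. The VEGF receptors Kdr and Flt1 differed by -0.016 and 0.020, Pecam1 by 0.015 and the endothelial cadherin Cdh5 by -0.064, each less than its SE, and Sox7 and the tight junction gene Cldn5 by -0.25 and -0.24. Without control 3 the endothelial list passed downwards, with a median of -0.072 (camera, adjusted p = 0.017), and under quantile normalization its median was 0.0066 and Kdr differed by 0.029. Genes of tip cells and of the endothelial response to VEGF had a median of -0.015 over 22 measured members (camera, adjusted p = 0.92). Of these, Esm1, a secreted tip cell product, differed by 0.22 and Rgcc by -0.23, and no member passed adjusted over the list alone. The list of VEGF ligands and receptors other than Vegfa had a median of -0.029 over 9 members (camera, adjusted p = 0.95). In it Vegfc, at 0.34 with an SE of 0.065, was higher adjusted over the list alone, while Vegfd differed by -0.080. Notch and arterial genes had a median of -0.040 over 16 members (camera, adjusted p = 0.92), with the Notch targets Hes1 and Hey2 at 0.28 and 0.20. Pericyte and smooth muscle genes had a median of -0.016 over 15 members (camera, adjusted p = 0.92), with the pericyte receptor Pdgfrb at -0.10, Notch3 at 0.10 and Tagln at 0.15, and their median was 0.040 without VEGF 3 and -0.11 without the 3 arrays with high thalamic values. Blood-brain barrier genes had a median of -0.047 over 21 members (camera, adjusted p = 0.92), with the lipid transporter Mfsd2a at -0.20, and Lef1, a Wnt effector shared with the thalamus list, at 0.36. The median of the barrier list was -0.092 without control 3 and -0.0014 without control 2, and it reached 0.0049 among the alternatives.

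Matrix and protease genes gave single differences. The basement membrane list did not pass (14 members, median 0.023, camera, adjusted p = 0.10), and fibronectin, Fn1, differed by 0.26 and perlecan, Hspg2, by 0.15. It passed upwards without control 2 (median 0.033, camera, adjusted p = 0.032), without control 4 (0.026, adjusted p = 0.034), without VEGF 3 (0.025, adjusted p = 0.011), with a sex index as a covariate (0.028, adjusted p = 0.041), without the 3 arrays with a female pattern (0.035, adjusted p = 0.048) and under quantile normalization (0.035, adjusted p = 0.021). Extracellular proteases and their inhibitors did not pass either (19 measured, median -0.0079, camera, adjusted p = 0.46). Adjusted over the list alone 3 members were higher, Adamts9 at 0.16, Adam17 at 0.19 and Mmp14, a membrane-bound matrix metalloproteinase, at 0.15, the last chosen after its value was seen. The gelatinase Mmp9 differed by -0.21 with an SE of 0.159. Cathepsins and cystatins had a median of -0.0016 over 16 members (camera, adjusted p = 0.92), with Ctsc at 0.30, Ctso at -0.17 and Ctsb at 0.039. Apoptosis genes had a median of 0.0049 over 18 measured members (camera, adjusted p = 0.29), with the death receptor Tnfrsf10b at 0.33 and cytochrome c, Cycs, at 0.14. The hypoxia and glycolysis list had a median of 0.045 over 25 measured members (camera, adjusted p = 0.12). It passed upwards without control 4, with a median of 0.071 (camera, adjusted p = 0.027). Its members Ndrg1 and the lactate transporter Slc16a3 went opposite ways, at -0.58 and 0.37.

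None of the lists of glial, immune and surrounding cells in this paragraph passed the test on the 8 arrays. Microglia and macrophage genes had a median of -0.032 over 29 measured members (camera, adjusted p = 0.50). Lyz2 was higher adjusted over the list alone, the other 28 members did not pass, and the microglial receptor P2ry12 differed by -0.28. The microglia list passed upwards with array weights (median 0.018, camera, adjusted p = 0.010), with the erythroid covariate (0.018, adjusted p = 0.045) and without the 3 arrays with high thalamic values (0.026, adjusted p = 0.024). Astrocyte genes had a median of -0.071 over 16 members (camera, adjusted p = 0.81), and adjusted over the list alone 2 members were higher and 2 lower, among them Id3 at 0.43 and the folate enzyme Aldh1l1 at -0.68, while Gfap, whose promoter drives the transactivator, differed by -0.082 with an SE of 0.053. Oligodendrocyte precursor genes had a median of -0.096 over 9 members (camera, adjusted p = 0.29), with Gpr17 at -0.12 and Lhfpl3 at -0.28. They passed downwards with the thalamus list mean as a covariate (median -0.12, adjusted p = 0.018) and without the 3 arrays with a female pattern (-0.11, adjusted p = 0.040), while without VEGF 3 their median was -0.037 (adjusted p = 0.37). Choroid plexus genes had a median of -0.079 over 11 measured members (camera, adjusted p = 0.29), with the water channel Aqp1 at -0.17 and the folate receptor Folr1 at -0.14. Their list passed downwards with the thalamus list mean as a covariate (median -0.25, adjusted p = 5.1e-05) and without the 3 arrays with high thalamic values (-0.10, adjusted p = 0.024). Genes of meninges and fibroblasts had a median of 0.019 over 17 members (camera, adjusted p = 0.92), with Slc6a13 at -0.49 and Crabp2 at 0.21, and the list passed upwards without VEGF 3, with a median of 0.15 (camera, adjusted p = 0.011). Inflammation and leukocyte adhesion genes had a median of -0.017 over 17 measured members (camera, adjusted p = 0.92), with Cd44 at 0.18 and Serpina3n at -0.16. Interferon response genes had a median of 0.024 over 11 measured members (camera, adjusted p = 0.38), with Ifitm3 at 0.26 and Rsad2 at 0.36, a difference that rests on VEGF 1 at 0.887 against 0.025 to 0.046 in the other 3 VEGF arrays, and the list passed upwards without the 3 arrays with a female pattern (median 0.070, adjusted p = 0.0064). Immediate early genes had a median of -0.041 over 14 members (camera, adjusted p = 0.71), with the phosphatase Dusp1 lower adjusted over the list alone at -0.19 and Egr4 at -0.13. The median of this list was -0.077 without control 3 and -0.0022 without control 2. The median, the mean and the direction of the camera test did not share a sign in the lists of proteases, microglia, tip cells, pericytes, meninges, cathepsins and VEGF ligands and receptors. Under quantile normalization the medians of the tip cell, protease, cathepsin and inflammation lists were 0.0018, 0.014, 0.0041 and 0.0054.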

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

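All tests of explanations in this part, and the counts over other splits of the arrays, were chosen after the results were seen. In 246 checks of whether 1 of the 4 arrays of a group stood far from the other 3, over the named genes and the list means, 14 arrays did, where chance would give 12.3.

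VEGF 3 stood below the rest of its group in 4 list means. They were interneurons and ventral forebrain at -0.624, synapse and neuronal maturation at -0.285, meninges and fibroblasts at -0.410 and endothelial at -0.172. The same array stood apart in Camk2a at -0.509 and in Pdgfrb at -0.442. VEGF 4 stood nearer to control than the rest of its group in Unc5d, at -0.104 against -0.44 to -0.42, and in Ndrg1, at 0.130 against -0.73 to -0.66. VEGF 1 stood apart in Hspa5, at -0.0057, and in the interferon-induced gene Rsad2, at 0.887. Among control arrays, control 2 stood apart in Lef1 at 0.0741 and in the inflammation and leukocyte adhesion list at 0.104, control 3 in Vegfd at -0.0623, and control 4 in Flt1 at 0.0787.

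The first pattern is that Vegfa was not higher in the VEGF-labelled arrays. An exchange of labels between the groups would leave some arrays with high Vegfa if the probe set reads the transgene, and the largest gap between neighbouring arrays was 0.0513 on the log2 scale. That argues against an exchange of labels as the reason only if the probe set reads the transgene and the transgene was active. A probe set that misses the transcript of the transgene may still be the reason, and it cannot be told apart from a transgene that was not active, since the genes that VEGF induces in endothelium did not pass in either direction as a list (camera, adjusted p = 0.921). A biological reason, weak or local induction of the transgene at this age, was not tested and stays open.

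The second pattern is the lower value of forebrain neuron genes. For the interneuron and ventral forebrain list, 1 of the 35 splits of the 8 arrays, the real one, gave a difference of list means as large, 0.446 against 0.370 for the highest other split, but as 1 of 30 lists (exact permutation, adjusted p = 0.381) its shift does not exclude chance. With the thalamus list mean as a covariate the difference was -0.481 with an SE of 0.176 (-0.306 with an SE of 0.096 without VEGF 3), against -0.446 without the covariate. Its 95% interval lay below 0, though with 1 array left out the interval stayed below 0 in only 2 of 8 cases. The covariate thus did not shrink the difference. A mean of 8 genes measures thalamic tissue imperfectly, however, so such tissue in some arrays is not excluded as the whole cause. For the projection neuron list the same covariate left -0.128 with an SE of 0.041, its interval also below 0 (in 5 of 8 cases with 1 array left out). The difference without the covariate was -0.231, so the covariate took up part of it. Since the covariate is imperfect, thalamic tissue stays open as part of the cause or the whole of it. A piece with less ventral forebrain is a candidate explanation for the interneuron list. Of measured striatal and other ventral forebrain genes outside that list, such as Ppp1r1b and Lhx8, 8 of 8 were lower too. Their mean difference was -0.27 with an SE of 0.082. Within the list, 6 of 6 genes of ventral territory were lower, with a mean difference of -0.318 and an SE of 0.132. A subset of 4 interneuron genes of the list differed by -0.737 with an SE of 0.208. That subset is only part of the list, and its difference was not tested against the others. An effect of VEGF on ventral forebrain, or of another difference in genotype between the groups, would give the same and stays open.

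The third pattern is the higher Hmox1. Red cell RNA as the whole cause is argued against by the erythroid list mean as a covariate, which left a difference of 0.620 with an SE of 0.106. With the microglia and macrophage list mean as a covariate the difference was 0.686 with an SE of 0.083, but that mean hardly differed between the groups, so the covariate could remove nothing. RNA of macrophages cannot be told apart from other causes, since Lyz2 was higher by 0.44 and microglial P2ry12 differed by -0.28. A change in which cells express Hmox1, or in how strongly, may remain, under VEGF or through another difference in genotype. Since 0 genes passed over all arrays the difference itself is a hypothesis.

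Other splits of the 8 arrays set a limit on the remaining results. The real split gave 0 genes past the adjusted threshold, a count that all 35 splits reach by definition, and the highest other gave 1. For genes at an unadjusted p under 0.05, 3 of 35 splits gave as many (2484 against 2794 for the highest other), and for genes whose groups do not overlap also 3 (1364 against 1499). As many lists passed camera in 15 splits (9 against 18), so that the preset correlation calls many lists in splits that mix the groups, and points to a structure of the arrays that the groups do not follow. For the synapse list the real split alone reached its difference (1 of 35, 0.136 against 0.135), but as 1 of 30 lists (exact permutation, adjusted p = 0.381) this does not exclude chance either. Chance could not be excluded for projection neurons (2 of 35, 0.231 against 0.239), erythroid (2 of 35, 0.2391 against 0.2395), unfolded protein response (3 of 35, 0.0766 against 0.0996), radial glia (3 of 35, 0.0792 against 0.0937), mitosis (4 of 35, 0.190 against 0.247), DNA replication (4 of 35, 0.148 against 0.193) or thalamus and hippocampus (7 of 35, 0.415 against 0.660).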

How the results depend on the processing

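The alternatives with the first probe set of each gene, the thalamic covariate, the omission of 3 arrays and the exact permutation of list means were chosen after seeing the data. The count of 0 genes past the threshold in limma was 1 without the 3 arrays with high thalamic markers and ranged from 0 to 10 when each array was left out, and it was 0 under the other alternatives run. Genes at an unadjusted p under 0.05 numbered 1583, 550 higher and 1033 lower, without the 3 arrays with a female pattern. They ranged from 1526 to 2881 when each array was left out, with 479 to 1217 higher. For lists, 0 passed with an estimated correlation, with the directional fry test or with exact permutation, 0 up and 0 down. The medians, which these tests leave as they are, were -0.35 for interneurons, -0.18 for projection neurons, -0.16 for synapse, 0.40 for thalamus, 0.21 for mitosis, 0.14 for DNA replication, 0.14 for erythroid, 0.072 for unfolded protein response and 0.057 for radial glia. The first of these tests estimates how far the genes of a list vary together, which widens its error. With the erythroid list mean as a covariate the medians were -0.033 for erythroid, which the covariate removes by construction, -0.16 for synapse (adjusted p = 0.14) and 0.20 for thalamus (adjusted p = 0.18), and the cause was not tested for the last 2. With the thalamus list mean as a covariate 5 lists passed downwards, the main 3 with oligodendrocyte precursors and choroid plexus, for which the cause was not tested, and the thalamus median was 0.0064, again by construction. The synapse median ranged from -0.20 to -0.087 when each array was left out, and the list did not pass without VEGF 3. Over 198 recomputed values of the 9 lists, 166 kept direction and side of the threshold, 32 did not pass and 0 turned past the threshold. Those that did not pass include every one of the 9 lists with an estimated correlation, with fry and with exact permutation. The other values come from camera at the same preset correlation, so their agreement says nothing about the choice of test. Among the other lists 18 of 462 values passed, and in 80 the direction of the test changed. Of 1840 values of named genes other than Vegfa 4 passed, all without VEGF 4, and 21 changed sign, in 7 genes (Pecam1, Kdr, Flt1, Rsad2, Gfap, Pdgfrb and Cdh5). Vegfa ranged from -0.0087 to 0.078, so that it too changed sign, with a lowest adjusted p of 0.58. The filter on dim probe sets was not run, and the highest probe set of each gene was replaced by the first, because centred values hold no levels. Signal over background therefore limits these results to an unknown degree.

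The labels give both groups the replicate numbers 1 to 4. Deviations of arrays with the same number correlated between -0.13 and 0.45, over 0.1 in 2 of 4 pairs, and 4 of 8 arrays correlated best with their own number. With 4 pairs, these values cannot tell whether the numbers pair the arrays. With the replicate number as a block limma gave 0 genes past the threshold, 2649 at an unadjusted p under 0.05, 1074 higher and 1575 lower, and 9 lists.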

Other observations

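The genes below were chosen after their values were seen, as those with the widest range over the 8 arrays, sex-linked genes left out.

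The transcription factor genes Tcf7l2, Gata3 and Olig3 were highest in VEGF 1 and VEGF 2. Tcf7l2, a Wnt effector of the thalamus, was at 1.65 and 1.59 in these arrays and at 0.68 in control 2, against -0.86, -0.47 and -0.84 in the other control arrays and -0.74 in VEGF 4. Gata3 was at 1.65 and 1.70 in VEGF 1 and VEGF 2 and between -0.18 and 0.22 in the control arrays. Olig3 was at 0.94 and 1.05 in VEGF 1 and VEGF 2 and between -0.75 and 0.34 in control.

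The neuropeptide genes Sst, Tac1 and Penk were lowest in VEGF 3. Sst, the somatostatin gene of a class of interneurons, was at -1.32 there, Tac1, a tachykinin precursor, at -1.63 and Penk, the enkephalin precursor, at -1.14. Mc4r, a melanocortin receptor, differed between the groups by -1.41, with control 1 at 1.45 and VEGF 1 at -1.14. Differences between the groups in Tac1 and Penk were -0.53 and -0.52, and both rest largely on VEGF 3. In VEGF 1, VEGF 2 and VEGF 4, Tac1 was at -0.22, 0.33 and -0.086, against -0.096 to 0.41 in control. Penk was at -0.11, -0.14 and 0.16 in these arrays, against -0.095 to 0.55 in control.

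Acot7 and AA388235 split the arrays into values far apart. Acot7, an acyl-CoA thioesterase, was at 0.99 in control 4, 1.32 in VEGF 1, 1.11 in VEGF 3 and 1.94 in VEGF 4, and between -1.49 and -0.99 in the other 4 arrays. AA388235 was at -2.16 in VEGF 3 and -2.27 in VEGF 4 and between -0.024 and 0.22 in the other 6. All 4 VEGF-labelled arrays lay below the control arrays, but VEGF 1 at -0.013 and control 2 at 0.013 lay close together. The first 3 principal components of all genes, sex-linked ones included, held 36.5%, 28.1% and 15.4% of the variance. On the first, the 3 arrays with a female pattern lay highest, VEGF 2 at 13.4, VEGF 3 at 14.7 and control 3 at 2.59. VEGF 1 lay at 0.95, and VEGF 4 lay at -2.63 with the other control arrays below it.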
